A study of Mus musculus with 4 samples.

How the data were processed

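Brains of mice at postnatal day 5 were sectioned coronally at a thickness of 10 µm, 24 h after the whiskers of the right side of the snout had been lesioned at postnatal day 4. The tissue was measured by MERFISH, an imaging assay that reads barcoded RNA molecules of a chosen gene panel in place by repeated rounds of hybridization. Each of the 4 coverslips carried 1 wild-type section and 1 section of a mouse lacking Cx3cl1, the gene of the chemokine fractalkine. Coverslips 1 and 2 were male and coverslips 3 and 4 were female. The deposited values are counts of decoded transcripts per segmented cell, for 140 genes and for 40 blank barcodes, which match no probe and measure false decoding. The deposited files also give the volume and the centre of each cell as other measures, whose unit is not given per the file headers; distances below are therefore in the coordinate units of the files. The decoding and segmentation software of the authors, its version and its filters are not given in the sources used here. Every count was checked to be a whole number of 0 or more, and no normalization had been applied to the counts.

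No column gives the genotype, hemisphere, brain region, section or cell type of a cell. Genotype, hemisphere and region were not assigned; sections were separated by position, and cells were grouped by marker counts, as described below. The 16 fits planned before the data were examined, which compared hemispheres and genotypes in microglia, astrocytes, excitatory neurons and all cells, were therefore not run, nor were the 104 alternatives fixed for them. No paired analysis was run because the files do not say which section of a coverslip is the wild-type section or which side of a section is which hemisphere. Genotype was not inferred from the measured level of Cx3cl1. The planned tests of shares, distances and Cx3cl1 between genotypes and hemispheres were likewise not run, and those measures were reported as values per coverslip or per section. The comparisons in the text, their tests and their 21 added alternatives were chosen after the files were seen. The gene lists, the cell type markers and the rule for the genes named had been fixed before the data were examined; the rule that names clusters was set afterwards.

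In all, the files held 863580 cells and 192921713 gene counts. Cells with fewer than 20 gene counts, 7.96% of all cells, were left out, which kept 794833 cells. The sections of a coverslip were told apart by position alone, as the 2 largest connected pieces of squares of side 100 with at least 4 cells each. Low-signal squares, of side 200 and with at least 20% of cells below the count minimum, held 3.08% of the kept cells, and alternatives left them out.

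Cell populations came from the 32 panel genes on the fixed marker lists. Counts were scaled to 200 per cell and log-transformed. A neighbour graph (15 neighbours) of 60000 cells, 15000 drawn per coverslip, was clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), and every kept cell took the majority cluster of its 15 nearest cells among 16000 of these. A first clustering on markers scaled to unit variance was replaced after its clusters were inspected and before any comparison was made; the comparisons were not run on it. Resolutions 0.5 and 2 were alternatives. A cluster was named after a cell type, with the ending "-like", when at least 3 markers of that type were 2-fold higher than in the other cells and when that type had more markers among its 10 leading genes than any other type. Clusters that met no name kept a number, and clusters of the same name were joined. Cluster 13, with a median of 34 counts per cell, was left out of the populations because its counts were low, which left 13 populations; its cells remain in the sums over all cells.

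Counts were summed per coverslip and population, so that the replicate was the coverslip (n = 4) and not the cell. The sums of all populations entered the same fit and were treated as independent apart from the coverslip block. The SE and p-values of the population comparisons therefore draw on the spread over all populations. They do not measure the spread of a single comparison over the 4 coverslips. Each sum pools a wild-type and a knockout section. Populations were compared with edgeR 4.0.16 (R 4.3.3): quasi-likelihood fits with coverslip as a block, the summed cell volume as offset, and the glmTreat test against a 2-fold difference. Values were adjusted over 108 genes by the Benjamini-Hochberg method at 0.05. The 32 clustering genes were left out of these tests because they defined the populations. A gene was called only if its count per cell lay above that of all 40 blanks on every coverslip in the population with the higher level, or, for a gene lower than the mean of the others, in at least 1 of those others. The volume offsets and the 2-fold threshold were fixed before these fits were run. Female and male coverslips were compared over all 140 genes with TMM factors, a test against no change, and DESeq2 1.42.0 as a second tool. Lists with at least 3 tested genes were tested with fry and with camera at an estimated correlation (limma 3.58.1). The fry test asks whether the genes of a list differ from no change, so a shift shared by all tested genes also enters it. The camera test asks whether a list differs from the other tested genes. Of the 17 fixed lists, 15 had members on the panel, 4 had enough tested genes for the population comparisons and 8 for the comparison of sexes.

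Distances ran from each cell to the nearest microglia-like cell of the same section. The median was divided by the median over 20 random relabellings of the section's cells, and the ratios of the 4 coverslips were tested against 1 with an exact two-sided sign-flip test, which cannot give a p below 0.125. Astrocyte-like cells within 25 units of a microglia-like cell were compared with those 75 to 150 units away, with edgeR and TMM factors on all 140 genes, with coverslip as a block. That comparison was repeated with section as the block, within squares of side 200 and in a random subset of the same cell numbers.

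The naming rule fixed before the data were examined took, per comparison, the 5 genes higher and the 5 lower with the smallest adjusted p that moved the same way in every coverslip. Its words on pairs of sections were read as coverslips, and not every gene that it takes is named in the text. It added the 3 smallest p-values where fewer than 3 genes passed, the 4 members of a list with the smallest p, up to 3 genes for each other population, and Cx3cl1 and Cx3cr1; Cx3cr1 is a clustering gene and so was not tested between populations. Any further gene is named because a count was small or because it belongs to a population or list described beside it, and was chosen after its values were seen.

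The tests were checked on simulated counts with known changes. With 20 genes changed, the test against 2-fold called 20 at 4-fold in both comparisons tried, and 0 at 1.5-fold. At 2.5-fold it called 20 for microglia-like cells against the others and 18 for astrocyte-like against microglia-like cells. These simulated populations shared 1 rate per volume apart from the changed genes and were fitted with volume offsets. The check therefore does not cover the choice of scaling. The comparison of sexes called 97.5% of genes changed 2-fold and 0.75% of unchanged genes. The comparison of near and far cells called 19 of 20 genes changed 1.25-fold and 4 of 120 unchanged genes. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.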

Results

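MERFISH counts of 140 genes were measured in 863580 segmented cells on 4 coverslips of neonatal mouse brain, each with 1 wild-type and 1 Cx3cl1 knockout section. The panel covers Wnt signalling, a family of secreted ligands and their receptors, together with markers of brain cell types. Gene counts totalled 33519204 and 37922304 on the male coverslips 1 and 2, and 44924894 and 76555311 on the female coverslips 3 and 4. The median count per cell was 123, 147, 175 and 268 on coverslips 1 to 4. Blank barcodes, which measure false decoding, made up 1.16% to 1.48% of all counts. Meg3, a maternally expressed noncoding RNA abundant in neurons, took 24.9% to 28.9% of the gene counts. The study's design contrasts genotypes and the hemispheres of lesioned and intact whiskers; since the files do not say which cells belong to which, those contrasts were not analysed here. All values below pool both sections of a coverslip unless a section is named.

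The cells fell into 13 populations, each present on all 4 coverslips, and the SD of a share over coverslips ran from 0.0973 to 1.48 percentage points. Inhibitory neuron-like cells, which join a cluster led by the GABA-synthesis genes Gad1 and Gad2 and a smaller cluster of 28035 cells led by Sst and Pvalb, made up 17.3% ± 0.862 of kept cells (SD, n = 4). Astrocyte-like cells, led by the glutamate transporter gene Slc1a3, the water channel gene Aqp4 and Gfap, made up 15.2% ± 0.757. Cells resembling oligodendrocyte precursors (OPC-like), led by Pdgfra and Sox10, made up 6.29% ± 0.703. Microglia-like cells, led by the receptor genes Csf1r and Cx3cr1 and the complement gene C1qa, made up 1.46% ± 0.109. Of the numbered clusters, cluster 8 (6.14% ± 0.138) was led by the vessel genes Cldn5 and Pecam1 and by Pdgfrb. Cluster 11 (2.08% ± 0.346) was led by Mrc1 and Lyve1, markers of macrophages at brain borders, but mixed unlike cells, and cluster 14 (0.576% ± 0.0973) by Enpp6. The layer genes Rorb and Cux2 led cluster 9 (4.00% ± 0.357), Cux2 led cluster 6 (6.52% ± 0.751) and Slc17a6, a vesicular glutamate transporter, led cluster 3 (11.5% ± 0.582). Bcl11b led cluster 2 (12% ± 1.48) and, with Gad2, cluster 4 (8.03% ± 0.611); no marker led cluster 5 (7.79% ± 1.04) by 2-fold.

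**Figure D1:**
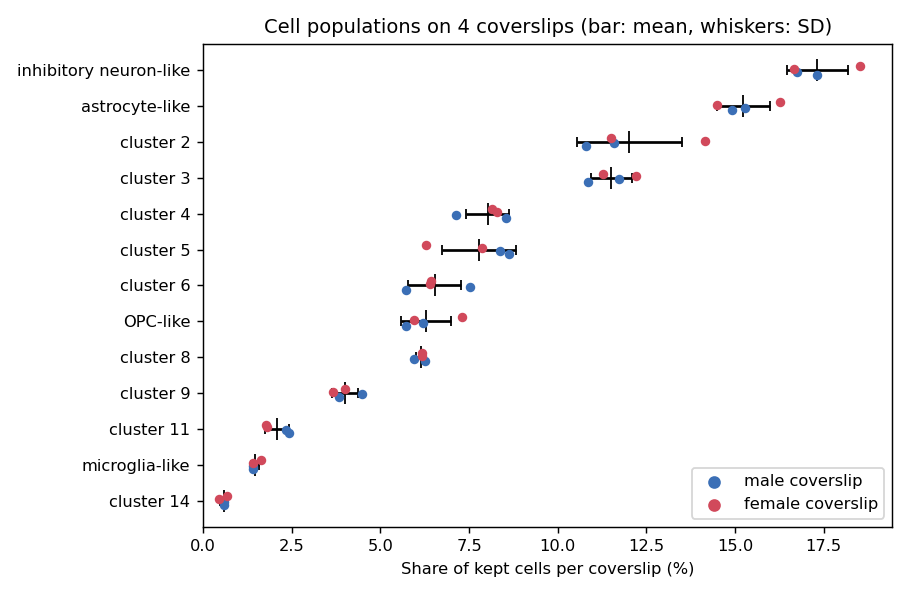
Share of kept cells (%) of each of the 13 populations, with a point per coverslip coloured by sex, the mean as a bar and the SD as whiskers. Inhibitory neuron-like cells held the highest mean share, 17.3%, and cluster 14 the lowest, 0.576%.

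Counts of a marker in another population limit the background that a population's values can carry. Stray counts were not separated from expression there or from mixed clusters. Slc1a3 reached 7.94% ± 0.468 of its astrocyte-like level in microglia-like cells, Aqp4 reached 9.65% ± 0.748 and Aldh1l1 reached 11.2% ± 1.07 (SD, n = 4). Csf1r reached 0.657% ± 0.0817 of its microglia-like level in astrocyte-like cells, and Cx3cr1 reached 0.940% ± 0.0632. Microglia-like cells held Mrc1 at 56.5% ± 4.81 of the level in cluster 11, but Lyve1 at 3.55% ± 0.709. Cluster 11 mixed cells with Mrc1 and cells almost without it (4.67 and 0.101 counts per cell at double the resolution). Its Mrc1 share is therefore not read as background. Gad1 reached 6.17% ± 0.500 of its level in inhibitory neuron-like cells in microglia-like cells, and 5.17% ± 0.568 in astrocyte-like cells.

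The comparison of astrocyte-like with microglia-like cells asks which genes of the Wnt pathway and of cell contact separate the partners of the crosstalk that the study concerns. Astrocyte-like cells held far more of several Wnt receptor and effector genes. Daam2, a formin of the Wnt pathway, was 16.3-fold higher (log2 4.02 ± 0.11, SE, adjusted p = 2.6e-31) at 2.95 ± 0.696 against 0.191 ± 0.0437 counts per cell (SD, n = 4). The Wnt receptor gene Fzd2 was at least 13.2-fold higher (log2 3.72 ± 0.14, adjusted p = 3.0e-25). Its 0.0610 counts per cell in microglia-like cells lay below the highest blank there (0.162), so this fold is a lower bound. The glypican gene Gpc5 was 9.09-fold higher (log2 3.18 ± 0.08), and Ezr, whose product links membrane to actin, was 6.19-fold higher (log2 2.63 ± 0.08). The transcription factor gene Etv4 was at least 9.95-fold higher (log2 3.32 ± 0.13), as its 0.124 counts per cell in microglia-like cells also lay below the highest blank. Lower in astrocyte-like cells were the integrin gene Itgam (log2 -3.75 ± 0.12, adjusted p = 9.8e-28), the leukocyte gene Ptprc (log2 -1.42 ± 0.11, adjusted p = 4.0e-05) and the apoptosis gene Bcl2l11 (log2 -1.17 ± 0.11, adjusted p = 0.045).

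Of 108 genes, 35 were at least 2-fold higher and 3 at least 2-fold lower in astrocyte-like cells, and each of them differed in the same direction on 4 of 4 coverslips. Among 30 genes for Wnt receptors and the pathway inside the cell, 12 were higher, 0 lower and 18 not called; the higher genes included Tcf7l1 (log2 2.92) and Fzd1 (log2 2.69). Among 19 genes for Wnt ligands and their secretion, 5 were higher: Wnt7a (log2 2.85), Wnt5a (log2 2.07), Wnt7b (log2 1.94), Wnt8b (log2 1.80) and Wnt3 (log2 1.77). Of 6 genes for Wnt antagonists, Sfrp1 alone was higher (log2 2.68). In microglia-like cells 2 of the 19 ligand genes and 0 of the 6 antagonist genes lay above every blank. For a gene not above every blank there, the difference is a lower bound. Of 5 genes for contact of astrocytes with synapses, 4 were higher, namely the glypican genes Gpc4 (log2 2.47), Gpc5 and Gpc6 (log2 2.09), and Ezr. Adjusted over the list alone, the counts higher were 12, 5, 1 and 4. The list test fry, against no change, gave adjusted p = 1.4e-20, 2.4e-16, 1.4e-20 and 1.1e-30 for these lists. The camera test, against the other genes, gave adjusted p = 0.954, 0.954, 0.954 and 0.214. The median log2 difference was 0.88 for receptors and 0.91 for ligands, where that of all 108 genes was 0.91. Cx3cl1 lay at log2 -0.51 ± 0.10 and did not pass the 2-fold test (adjusted p = 1.00); this value averages over sections whose Cx3cl1 levels lay far apart.

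The median log2 difference over all 108 genes was 0.91 with volume offsets. With TMM factors the median was 0.08, and 21 genes were higher and 7 lower; with library totals the median was 0.52, and 32 were higher and 5 lower. At double the clustering resolution, where the microglia-like class took in cells with Mrc1 and Lyve1, 14 were higher and 13 lower.

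**Figure D2:**
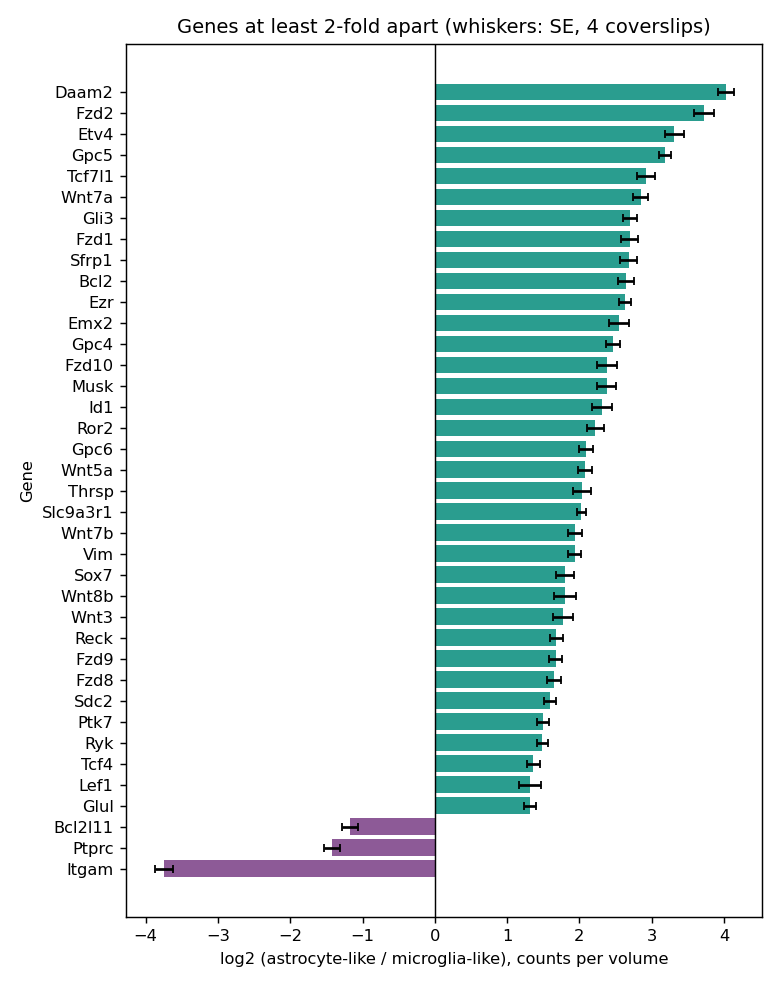
The log2 ratio of counts per volume in astrocyte-like over microglia-like cells, as bars, for the genes at least 2-fold apart. Whiskers give the SE from the fit of all populations together (4 coverslips). Of these genes 35 were higher in astrocyte-like cells, up to 4.02 for Daam2, and 3 were lower, down to -3.75 for Itgam; TMM factors gave 21 higher and 7 lower.

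Astrocyte-like cells were also set against the mean of the other 12 populations, to show what marks them among all cells of these sections. Daam2 was 8.67-fold higher (log2 3.12 ± 0.05, adjusted p = 8.3e-37) and Apoe, the gene of the main lipid carrier of the brain, was 7.38-fold higher at 34.9 ± 10.4 counts per cell (SD, n = 4). The syndecan gene Sdc4 was 6.78-fold higher, Slc9a3r1 6.69-fold and Ezr 5.43-fold, with SE of at most 0.05 on the log2 scale. These folds are against a mean of log levels. In counts per cell Ezr lay at 1.89 against a mean of 0.717 in the others. Lower were Meg3 (log2 -2.57 ± 0.08), Cx3cl1 (log2 -1.97 ± 0.08, adjusted p = 3.2e-17), the ligand gene Wnt16 (log2 -1.76 ± 0.08), the receptor gene Adgra2 (log2 -1.57 ± 0.07) and the glypican gene Gpc3 (log2 -1.42 ± 0.08). The value of Cx3cl1 averages over sections whose levels lay far apart.

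In all, 21 genes were at least 2-fold higher and 9 at least 2-fold lower in astrocyte-like cells than the mean log level of the others, each on 4 of 4 coverslips. Of 30 Wnt receptor and pathway genes, 6 were higher, including Fzd2 (log2 2.42) and Tcf7l1 (log2 1.5), and Adgra2 was lower. Of 19 ligand genes, Wnt7a was higher (log2 1.87 ± 0.06) and Wnt16 lower; none of the 6 antagonist genes was called, and Ezr and Gpc5 (log2 1.22) were higher among 5 contact genes. Adjusted over the list alone, the counts were the same. With fry the adjusted p was 8.1e-05 for receptors, 1.3e-05 for ligands, 8.8e-05 for antagonists and 6.5e-24 for contact genes. With camera, against the other genes, it was 0.954 for each. The receptor list had a median of -0.03 but a mean of 0.21 and an upward test. The downward tests of ligands and antagonists turned upward with TMM factors, and that of antagonists also with library totals. The median over 108 genes was -0.31, against 0.03 with TMM factors (28 higher, 4 lower) and -0.14 with library totals (24 higher, 5 lower).

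Microglia-like cells held little of most panel genes, with a few exceptions. The complement receptor gene Itgam was 16-fold higher than the mean of the other 12 populations (log2 4.00 ± 0.06, adjusted p = 1.4e-41) at 1.99 ± 0.668 counts per cell (SD, n = 4), Apoe was 5.97-fold higher at 29.7 ± 6.55, Sdc4 was 3.42-fold, the Wnt co-receptor gene Lrp5 was 3.05-fold (log2 1.61 ± 0.04, adjusted p = 2.3e-19) and Ptprc 2.26-fold higher. Apoe and Sdc4 were the 2 genes higher in microglia-like as well as in astrocyte-like cells. The largest evidence for a lower level was at the synaptic adhesion gene Nlgn2 (log2 -1.97 ± 0.05), Gpc5 (log2 -2.23 ± 0.07), Meg3 (log2 -2.40 ± 0.08), the Wnt7 receptor cofactor gene Reck (log2 -2.52 ± 0.08) and Gpc1 (log2 -2.14 ± 0.06). Cx3cl1 was lower as well (log2 -1.42 ± 0.08), as an average over unlike sections.

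Of 108 genes, 5 were at least 2-fold higher and 67 at least 2-fold lower in microglia-like cells, each on 4 of 4 coverslips, and the median log2 difference over all of them was -1.35. Lrp5 was the higher gene among 30 Wnt receptor and pathway genes, of which 21 were lower, including Ryk (log2 -2.05) and Ptk7 (log2 -1.76). Of 19 ligand genes 11 were lower, including Wnt16 (log2 -2.28), Porcn (log2 -1.85) and Wnt5a (log2 -1.80). Of 6 antagonist genes 5 were lower, including Sfrp5 (log2 -2.39) and Sfrp1 (log2 -1.97), and of 5 contact genes 4 were lower. Adjusted over the list alone, 22, 13, 6 and 4 genes of these lists were lower. With fry the adjusted p was 1.8e-23 for receptors, 3.3e-23 for ligands, 4.1e-26 for antagonists and 3.5e-30 for contact genes. With camera, against the other genes, it was 0.954 for each. The median was -1.33 for receptors and -1.33 for ligands, close to the -1.35 of all 108 genes. For receptors and ligands the fry result is therefore not told apart from a shift shared by all tested genes. Of the 19 ligand genes, 2 lay above every blank in microglia-like cells, and 0 of the 6 antagonist genes did. With TMM factors the median was -0.11, with 12 genes higher and 2 lower, and the receptor list turned upward. With library totals the median was -0.76, with 8 higher and 28 lower, and double resolution gave 22 and 30.

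Wnt genes differed among the other populations too. Of 19 ligand genes 12, and of 30 receptor and pathway genes 21, were at least 2-fold higher in at least 1 of the 13 populations; cluster 11 held 8 of the former and 16 of the latter, as a mixture. At double the resolution 48.6% of its cells fell into a cluster with Mrc1 and Lyve1 (4.67 and 2.66 counts per cell) and 42.9% into another almost without them (0.101 and 0.120). Per cell, the former held more Wnt5a (2.47 against 0.576), Wnt4 (4.42 against 0.279) and Fzd2 (1.38 against 0.762), and the latter more Ezr (11 against 0.642), Gpc3 (2.83 against 2.21) and Ror1 (0.992 against 0.622). In cluster 11 as a whole Wnt5a (log2 2.97 ± 0.05), Wnt4 (log2 2.60 ± 0.06), Fzd2 (log2 3.10 ± 0.07) and Ror1 (log2 3.28 ± 0.07) were higher, and so were Ezr (log2 4.27 ± 0.04) and Gpc3 (log2 3.49 ± 0.05). In cluster 8, with vessel markers, Fzd6 (log2 4.30 ± 0.08), Adgra2 (log2 3.56 ± 0.04), Fzd4 (log2 2.75 ± 0.06) and the Wnt-responsive factor genes Tcf7 (log2 3.72 ± 0.05) and Lef1 (log2 3.24 ± 0.08) were higher. Tcf7l2, another such factor gene, was higher in cluster 3 (log2 4.45 ± 0.07, 15.9 ± 7.40 counts per cell) and in cluster 14 (log2 3.56 ± 0.08). Wnt7b was higher in clusters 2 (log2 1.85 ± 0.06), 5 (log2 1.86 ± 0.06) and 9 (log2 1.87 ± 0.06), and Wnt2b in cluster 9 (log2 2.21 ± 0.07). Wnt7a was higher in cluster 4 (log2 2.04 ± 0.06) and, close to the limit of the 2-fold test, in OPC-like cells (log2 1.13 ± 0.06, adjusted p = 0.039). Inhibitory neuron-like cells held more Wnt7a per cell than OPC-like cells (0.691 against 0.495, log2 1.66). They were not called because Wnt7a did not lie above every blank there on every coverslip. Cx3cl1 was higher in cluster 4 (log2 2.19 ± 0.06), cluster 2 (log2 1.69 ± 0.06), inhibitory neuron-like cells (log2 1.5 ± 0.06) and cluster 5 (log2 1.39 ± 0.06). In cluster 5 it lay at 3.81 against a mean of 2.43 counts per cell in the others. All these Cx3cl1 values average over sections whose levels lay far apart.

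The numbers of genes higher and lower were 44 and 15 in cluster 11, 17 and 26 in cluster 8, 17 and 7 in cluster 9, 14 and 1 in cluster 3, 13 and 4 in cluster 2, and 9 and 8 in cluster 6. They were 7 and 0 in cluster 5, 5 and 9 in cluster 4, 4 and 26 in cluster 14, 3 and 2 in inhibitory neuron-like cells and 2 and 20 in OPC-like cells. TMM factors shifted these counts, to 28 and 24 in cluster 11, and to 4 and 0 in OPC-like cells, and scaling turned the balance of others. Cluster 9 had 6 and 15 with TMM factors and 10 and 14 with library totals, and cluster 2 had 6 and 9, and 7 and 8. Cluster 8 had 22 and 18 with TMM factors and 22 and 14 with library totals, and cluster 6 had 7 and 11, and 8 and 9. With library totals cluster 3 had 6 and 9, and inhibitory neuron-like cells 2 and 10. Beside the 0 lower genes of cluster 5 in the 2-fold test of edgeR, 23 genes were lower in the test against no change.

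**Figure D3:**
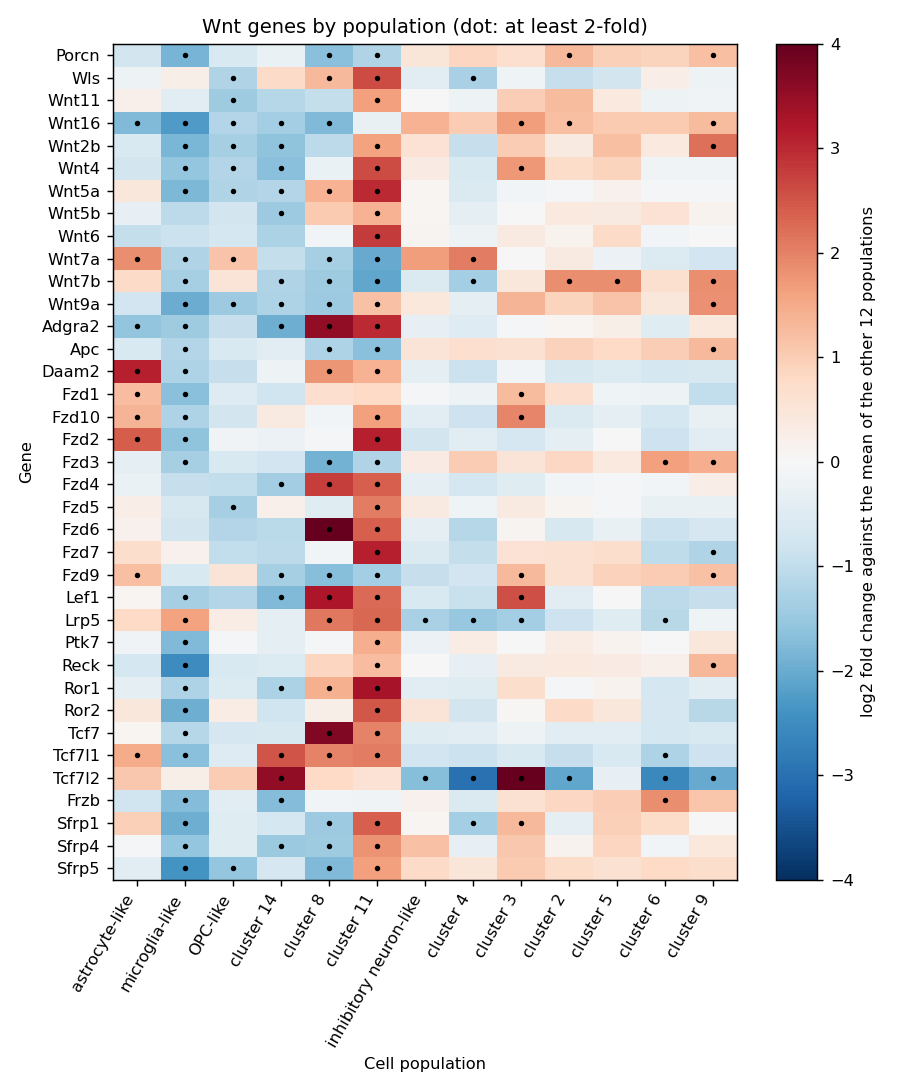
The log2 fold change of Wnt ligand, receptor and antagonist genes (vertical axis) in each population (horizontal axis) against the mean of the other 12, with volume offsets; a dot marks a difference of at least 2-fold. Cluster 11 holds 8 higher ligand genes and microglia-like cells 0; TMM factors shift a population's whole column, by moving the microglia-like median from -1.35 to -0.11.

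Female and male coverslips were compared because the labels give the sex, with 2 coverslips each, a size at which an exact permutation test of a single gene cannot go below p = 0.333. In all cells, Nfatc1 (log2 -1.02 ± 0.20, SE, adjusted p = 5.5e-05), Sfrp4 (log2 -0.73 ± 0.22), Wnt8a (log2 -0.72 ± 0.20), Gsk3b (log2 -0.66 ± 0.19) and Wnt16 (log2 -0.63 ± 0.18) were lower on female coverslips, each with adjusted p = 0.023 but the first. The proteasome gene Psmb4 (log2 0.57 ± 0.17, adjusted p = 0.023) and the glypican gene Gpc2 (log2 0.56 ± 0.18, adjusted p = 0.033) were higher. Gsk3b, a kinase gene of the Wnt pathway, had 111 counts per 10000 on female and 180 on male coverslips. Of these genes, Psmb4 overlapped between the sexes and the other 6 did not; over 140 genes 41.4% did not overlap, against 33.3% by chance. In astrocyte-like cells Gpc2 alone was called (log2 0.67 ± 0.18, adjusted p = 0.029), followed by Psmb4 (log2 0.59 ± 0.17, adjusted p = 0.0625) and Wnt16 (log2 -0.67 ± 0.22, adjusted p = 0.101), and 42.9% of genes did not overlap; library totals, volume offsets and leaving out low-signal squares each ended the call of Gpc2, at log2 0.69, 1.12 and 0.65. In microglia-like cells edgeR called 0 genes, with 11 at an unadjusted p under 0.05, and DESeq2 called 0; 39.3% did not overlap, and Sfrp4 lay at log2 -0.79 ± 0.28 (adjusted p = 0.221). Fitted alone, 9 of the 13 populations had at least 1 call with edgeR, which called Nfatc1 in 6, Gsk3b in 4 and Sfrp4 and Wnt8a in 3. In clusters 3 and 11 edgeR called 0, with 14 and 15 genes at an unadjusted p under 0.05, where DESeq2 called 15 and 2.

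Volume offsets ended all 7 calls in all cells, and all 7 values moved upward. The 5 lower genes went toward no change, such as -0.67 ± 0.30 for Nfatc1 and -0.22 ± 0.44 for Gsk3b. Psmb4 (1.07 ± 0.40) and Gpc2 (0.98 ± 0.34) had larger folds with a larger SE. Volume offsets leave in the higher median count per cell of the female coverslips (175 and 268, against 123 and 147). Values with these offsets are therefore not read gene by gene. Leaving out coverslip 1 or 4 gave 0, coverslip 2 gave 2 and coverslip 3 gave 6, but each such fit has 1 coverslip of a sex and takes its spread from the other sex, so it does not test the calls. Cx3cl1 lay at log2 -0.06 ± 0.19 (adjusted p = 0.925) and turned positive with volume offsets (0.34) or without coverslip 1 (0.12) or 4 (0.01); Cx3cr1 lay at log2 -0.26 ± 0.18 (adjusted p = 0.612) and at 0.15 with volume offsets. None of the 8 lists reached an adjusted p of 0.05 in microglia-like, astrocyte-like or all cells with fry (smallest 0.661) or with camera (smallest 0.947). For the difference between astrocyte-like and microglia-like cells, the edgeR test of its change with sex called 0 of 108 genes (smallest adjusted p = 0.221, 15 at an unadjusted p under 0.05; no other tool was run).

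Positions were used to ask how near astrocyte-like cells lie to microglia-like cells. The median distance to the nearest microglia-like cell was 65.0 ± 4.11 coordinate units for astrocyte-like cells (SD, n = 4 coverslips), and 1.00 ± 0.0193 times that of randomly relabelled cells (exact sign-flip p = 0.875). OPC-like cells lay at 66.2 ± 5.54 units, 1.02 ± 0.0172 times the relabelled distance (exact p = 0.250). Inhibitory neuron-like cells lay farther, at 71.3 ± 6.10 units and 1.10 ± 0.0259 times, beyond every relabelling in 8 of 8 sections (exact p of 2 in 16, the smallest that 4 coverslips allow). Between microglia-like cells the ratio was 1.04 ± 0.0241 (exact p of 2 in 16), and 0.998 with means in place of medians. With means the ratio was 1.02 ± 0.0108 for astrocyte-like cells and 1.02 ± 0.0109 for OPC-like cells (exact p of 2 in 16 each). For both of these populations the result of the test thus depended on the choice of medians or means.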

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

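All comparisons in this part, and both tests of their explanations, were chosen after the result was seen. A gap rule for single values far from the others was applied to 50 sets of 4 coverslips, and it marked 4; chance marks about 1 in 20 such sets. Microglia-like cells made up 1.62% of kept cells on the coverslip that stood apart, against a lowest share of 1.39%. Blanks made up 1.16% of counts on the coverslip that stood apart, against up to 1.48% on the others. Meg3 took 24.9% of gene counts on the coverslip that stood apart, against up to 28.9% elsewhere. The log2 difference of Daam2 between astrocyte-like cells and the other populations was 3.25 on the coverslip that stood apart, against a lowest value of 3.07.

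Signals also lay outside the comparisons. The 40 blanks held 1.34% of all counts. Cluster 13, left out of the populations, held 7498 cells with a median of 34 counts, of which 5245 lay on coverslip 1, 1220 on coverslip 2, 992 on coverslip 3 and 41 on coverslip 4; its leading genes included Sfrp4, Nfatc1, Wif1 and Wnt8a.

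In all cells, 7 genes differed between female and male coverslips, with Nfatc1, Sfrp4, Wnt8a, Gsk3b and Wnt16 lower and Psmb4 and Gpc2 higher on female coverslips. A background of counts that does not follow depth stays open: the 40 blanks had a median log2 difference of -0.0699 where the 5 lower genes had a median of -0.72, but single blanks ranged from -1.03 to 0.81, the lowest being the blank of most counts, and the bound against it was made stricter after these values were seen. Cells of very low count stay open, since 4 of the 7 genes, namely Nfatc1, Psmb4, Wnt16 and Gpc2, were still called in cells of at least 50 counts outside low-signal squares, a number between the bounds of under 3 and at least 5, which had been changed once the value was known and were then put back. The other 3 lost their calls as their folds shrank at like SE: Sfrp4 from -0.73 ± 0.22 to -0.49 ± 0.21, Wnt8a from -0.72 ± 0.20 to -0.55 ± 0.20 and Gsk3b from -0.66 ± 0.19 to -0.56 ± 0.19, and 4 of the 5 lower genes were among the 10 that led cluster 13, yet edgeR called Nfatc1 in 6 of the 13 populations, which exclude that cluster. With 2 coverslips of each sex, sex could not be separated from differences between coverslips, and sex itself stays open as untested.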

How the results depend on the processing

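The comparisons between populations and between sexes, and their alternatives, were chosen after the data were seen; the alternatives for shares, distances, Cx3cl1 and list tests with library totals, camera or a coverslip left out had been fixed before, though for other comparisons. None of the 104 alternatives fixed for the genotype and hemisphere fits was run. Of 389 alternative values for the counts of genes and of lists, the shares of astrocyte-like and microglia-like cells, the distance between them and the ratio of Cx3cl1 between sections, 317 stayed within their limits, 70 moved and 2 reversed. Of 1709 further values, for single genes, single lists, other shares and distances, and near and far cells, 1606 stayed, 9 moved, 80 were weaker, 4 were stronger and 10 reversed. Among these, of 1389 values for 119 named genes in a population, 1355 kept direction and call, 34 lost the call and 0 reversed. Of the 108 tested genes, 51 lay above every blank in microglia-like cells and 78 in astrocyte-like cells, from 28 in inhibitory neuron-like cells to 85 in cluster 11.

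Scaling moved most counts, by shifting a population's median. With TMM factors, genes higher and lower numbered 12 and 2 in microglia-like cells, 28 and 24 in cluster 11, 6 and 9 in cluster 2, 8 and 3 in cluster 3, 4 and 4 in cluster 5, 6 and 15 in cluster 9, 4 and 0 in OPC-like cells, and 21 and 7 for astrocyte-like against microglia-like cells. Lower genes numbered 4 in astrocyte-like cells and 12 in cluster 14. With library totals, they numbered 8 and 28 in microglia-like cells, 7 and 8 in cluster 2, 6 and 9 in cluster 3, 10 and 14 in cluster 9, and 7 and 0 in OPC-like cells. Lower genes then numbered 5 in astrocyte-like cells, 14 in cluster 14, 18 in cluster 4, 1 in cluster 5, 14 in cluster 8, 10 in inhibitory neuron-like cells and 5 in astrocyte-like against microglia-like cells. Counts per cell gave 1 lower gene in cluster 5 and 4 in cluster 9, and cells of at least 50 counts gave 1 in cluster 5.

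A resolution of 0.5 gave 5 lower genes in inhibitory neuron-like cells. Double the resolution, whose microglia-like class took in cells with Mrc1 and Lyve1, gave 22 higher and 30 lower genes in microglia-like cells, and 14 and 13 for astrocyte-like against microglia-like cells. DESeq2 gave 4 lower genes in cluster 9 and 1 higher in OPC-like cells. Without the blank rule, 6 genes were higher in inhibitory neuron-like cells and 5 lower in astrocyte-like than in microglia-like cells. Leaving out a coverslip gave 0 to 1 lower genes in cluster 5, 4 to 8 lower in cluster 9 and 1 to 2 higher in OPC-like cells.

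For sex, leaving out a coverslip leaves 1 coverslip of that sex, so those values do not test the calls. Astrocyte-like cells had 0 calls with library totals, volume offsets or no low-signal squares, and 0 to 3 without a coverslip. All cells had 0 calls with volume offsets, 4 with cells of at least 50 counts, 4 without low-signal squares and 0 to 6 without a coverslip. Cx3cl1 reversed to 0.34 with volume offsets and ranged from -0.22 to 0.12 without a coverslip, and Cx3cr1 reversed to 0.15 with volume offsets. Those offsets leave in the higher counts per cell of the female coverslips. Of 12 list tests with fry, 0 passed with camera, which sets a list against the other tested genes. It also reversed the direction of Wnt ligands in astrocyte-like against microglia-like cells, with the same median of 0.91. The direction of the fry test, though not the sign of the median, reversed for Wnt antagonists in astrocyte-like cells with library totals (median -0.27) and TMM factors (-0.104), for Wnt ligands there with TMM factors (-0.27), and for Wnt receptors in microglia-like cells with TMM factors (-0.0894).

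Among non-neuronal cells the shares were 47.9% astrocyte-like and 4.58% microglia-like, since the denominator was smaller, and double the resolution gave 14.1% and 2.60%. The distance ratio of astrocyte-like cells ranged from 0.997 to 1.01 without a coverslip, crossing 1. With means in place of medians it was 1.02, with the smallest exact sign-flip p that 4 coverslips allow, against 0.875 with medians. OPC-like cells also had a ratio of 1.02 with means and that smallest exact p, against 0.250 with medians. Between microglia-like cells the ratio was 0.998 with means. Cx3cl1 per cell differed at least 77.3-fold between the highest and lowest section, against at least 52.4-fold per 10000 counts, since the lowest lay below the highest blank. Except where a shift of the median, the class make-up or the denominator is named, the cause was not tested.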

Other observations

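The test with section as the block, that of a random subset and that of the excess of microglia genes in this part were chosen after the result was seen; the other 2 tests were written before it, although the comparison itself was chosen after the files were seen. Astrocyte-like cells within 25 units of a microglia-like cell (13344 cells) were compared with those 75 to 150 units away (41726 cells). The largest differences lay in the microglia markers Csf1r (log2 1.80 ± 0.08, SE), Cx3cr1 (log2 1.60 ± 0.06) and P2ry12 (log2 1.11 ± 0.07), which were higher near microglia-like cells. Gfap, an intermediate filament gene that rises in reactive astrocytes, was higher there too (log2 1.10 ± 0.05, 14.2 against 6.63 counts per cell), as was Vim (log2 0.54 ± 0.04), in 4 of 4 coverslips. Aqp4 (log2 0.24 ± 0.04), Sdc4 (log2 0.21 ± 0.03), Id1 (log2 0.19 ± 0.04) and Apoe (log2 0.18 ± 0.04) were higher by less, while the astrocyte markers Slc1a3 and Aldh1l1 were lower (log2 -0.12 each). The kinase gene Prkce (log2 -0.58 ± 0.04), Bcl11b (log2 -0.54 ± 0.06), Cx3cl1 (log2 -0.41 ± 0.06) and Gad1 (log2 -0.38 ± 0.04) were lower near microglia-like cells in 4 of 4 coverslips. Gad1 in astrocyte-like cells lay at 5.17% ± 0.568 of its level in inhibitory neuron-like cells. Whether these lower counts arose in the astrocyte-like cells themselves was not tested. Of 140 genes, edgeR called 35 higher and 42 lower. Each coverslip pools sections of unlike Cx3cl1 level, and near cells were 19.1% to 31.8% of the near and far cells of a section. With section as the block the calls were 32 and 50. In 4 of the 8 sections Cx3cl1 in astrocyte-like cells lay below the highest blank, so its difference there, as small as log2 -0.0638, is not read. In the other sections the Cx3cl1 difference ranged from log2 -0.69 to -0.48. Volume offsets gave 39 and 17, and leaving out a coverslip gave 30 to 32 and 21 to 32, the 21 without coverslip 2.

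Transcripts of the nearby microglia-like cell counted in the astrocyte-like cell stay open for the whole set of higher genes. Of the 35, 28.6% had more than 2-fold the astrocyte-like level in microglia-like cells, where under 50% was set as the bound against it. That bound cannot decide, since only 13 of the 140 genes had such a level and the share could not reach 50%. Of those 13 genes, 10 were called higher in near cells. For those 10 genes the same explanation may hold: 80.0% had an excess per cell within 2-fold of the median, 1.49% of the microglia-like level, among them Cx3cr1 and Csf1r, but not Bcl2l11 (17.2%) or Cldn5 (14%). Different parts of the brain in near and far cells may hold for part of the differences: within squares of side 200, 40 of the 77 calls (51.9%) remained, with a median size of 0.13 in place of 0.22. Fewer cells in that comparison stay open for the lost calls, since a random subset of equal numbers kept 51 of the 77 (66.2%, itself under the bound of 66.7% set for brain parts), but its median size was 0.22. Within squares Gfap fell from log2 1.10 to 0.65 and Vim from 0.54 to 0.19, so that most of the Vim difference was lost, and Aqp4 went from 0.24 to 0.30; no biological explanation was tested, and the selection of astrocyte-like cells by their marker counts, which include Gfap and Aqp4, was not tested either.

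Cx3cl1 was measured in each of the 8 sections. The labels place 1 wild-type and 1 knockout section on each coverslip without saying which is which, so the values are given by coverslip, with no genotype. Coverslip 1 held 5.23 and 274 Cx3cl1 counts per 10000 gene counts, coverslip 2 held 6.52 and 202, coverslip 3 held 6.15 and 236, and coverslip 4 held 6.83 and 201. The median of the 8 sections was 104. The values lay in separate clusters, with 1 section of each coverslip in each, and the highest was at least 52.4 times the lowest, whose count per cell lay below the highest blank. Counts per cell ranged from 0.0981 to 7.58, with a median of 2.09, where the highest blank of a section had 0.188 to 0.370. In microglia-like cells Cx3cl1 ranged from 3.23 to 88.4 per 10000 counts over the sections (median 35.5) and in astrocyte-like cells from 2.09 to 46.7 (median 21.2).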
